A study of Rattus norvegicus with 6 samples.

How the data were processed

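Poly(A) RNA from PC12 cells, a rat adrenal phaeochromocytoma line, was sequenced in 6 libraries, per the labels. The cells had been differentiated with nerve growth factor (NGF, 100 ng/mL) at passage 10 to 20 and were then exposed for 6 h to the solvent DMSO (3 libraries) or to WIN (WIN 55,212-2 mesylate, 5 µM), an agonist of the cannabinoid receptors CB1 and CB2 (3 libraries). Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

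The deposited table holds 1 column per library and 17384 rows named by gene symbol. Its values are CPM, read counts scaled to a common library total, and its lowest value was 0.0001, or up to 0.0003 for some genes, which was taken as an amount added by the authors. 4584 rows were at 0.0003 or less in all 6 libraries. The columns summed to between 538653 and 580865 CPM, short of the full CPM total, so the authors' library total included reads outside the listed genes. The libraries were made with a stranded kit, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.17, STAR 2.4.1d, Partek and genome build rn6. The annotation, the counting program, its strand setting, its treatment of reads that match several gene copies and any filter are not given in the sources used here. Values of paralogs with similar sequence and of antisense or overlapping genes are uncertain for that reason. 26 row names were dates in place of gene symbols, 2 of them repeated, and were kept out of the gene lists. No genome of that build was used, and no coordinates are given.

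After 0.0001 was taken off, between 95.6% and 96.1% of the values above 0.001 CPM lay within 0.05 of a whole multiple of 1 step per column. The step corresponds to totals of 29.8 to 36.1 M reads per library, of which 17.3 to 19.4 M fell in the listed genes. These depths are estimates from the values. The approximate reads were used to compare pairs of libraries by chi-square over genes with at least 10 reads, and no count-based test of WIN against DMSO was run.

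Pseudocount and filters were set on a CPM scale relative to the reads in the listed genes (mean column total 561546 on the deposited scale). The values were analysed as log2(CPM + 0.281), a pseudocount of 0.5 on the relative scale. 10020 genes with a mean of at least 0.562 CPM (1 on the relative scale) were tested with limma 3.58.1 in R 4.3.3 (a linear model of WIN against DMSO, empirical Bayes moderation with a mean-variance trend, Benjamini-Hochberg adjustment, threshold 0.05). Fold changes are on the log2(CPM + 0.281) scale, which understates the change of low genes. Levels are given as mean CPM ± SD with n = 3, and log2 fold changes as WIN minus DMSO ± SE. Genes listed at 0.0001 are given per library, without a fold.

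37 gene lists were fixed before the data were examined. They covered eIF2 and eIF2B subunits, eIF2 kinases and phosphatase regulators, other initiation factors, integrated stress response targets, cytosolic aminoacyl-tRNA synthetases, endoplasmic reticulum chaperones and ERAD (degradation of misfolded proteins), cholesterol synthesis, fatty acid synthesis, LXR and sterol efflux, and sphingolipid metabolism. They also covered immediate early, MAP kinase feedback, NGF-induced neuronal, catecholamine, dopamine receptor signalling, endocannabinoid, cAMP and CREB, synaptic vesicle, heat shock, NRF2, p53, apoptosis, mitotic, DNA replication, autophagy and lysosome, glycolysis and hypoxia, respiratory chain, ribosomal protein, NF-kappaB and interferon genes. The remaining lists were mitochondrially encoded transcripts, non-polyadenylated RNAs and markers of Schwann cells, fibroblasts, macrophages, adrenal cortex and endothelium. 30 lists with at least 4 tested members were tested with limma's camera (preset inter-gene correlation of 0.01, Benjamini-Hochberg adjustment over the 30 lists). Camera with a correlation estimated per list and the rotation test fry were run as alternatives. Counts adjusted over the list alone use the same limma p-values, adjusted within the list.

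The genes named were chosen by a rule fixed before the data were examined. They are the 10 largest rises and the 10 largest falls past the threshold among genes without overlap between groups, with at least 2.81 CPM (5 on the relative scale) in the higher group and no placeholder symbol. Eif2s1, Eif2b1, Cnr1, Cnr2 and Drd1 were always included. From each list came up to 4 members past the threshold with the largest change, or, where none passed, up to 2 with the smallest p. Genes named by choice after their values were seen are marked as such.

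The tests were tried on simulated data for WIN against DMSO over 10020 genes. With the per-gene spread of the real libraries, 4 of 58 genes changed by 1.5-fold, 42 of 73 changed by 2-fold and 62 of 69 changed by 4-fold were recovered, and 9 unchanged genes were called. The simulated noise was independent between genes and equally wide in both groups. In the real libraries differences are shared across genes and WIN spreads more than DMSO, so these rates may not hold for them. The alternatives were other pseudocounts (0.1 and 2 on the relative scale), no filter or a filter at 5 on that scale, median-of-ratios size factors, quantile normalization, equal column totals, no variance trend, array weights, the replicate number as a block, a minimum fold of 1.5, and leaving out each library in turn. Library subsets, a covariate for genes with long coding sequences and removal of ribosomal RNA were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.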

Results

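The transcriptomes of NGF-differentiated PC12 cells were measured after 6 h with the solvent DMSO (3 libraries) or with 5 µM WIN, a synthetic agonist of both cannabinoid receptors (3 libraries). The steps in the values correspond to 32.1, 33.0 and 32.4 M reads in the DMSO libraries and to 36.1, 32.4 and 29.8 M reads in WIN 1, WIN 2 and WIN 3. Within-group Pearson correlations of log2 values across genes, which are not independent replicates, were 0.996, 0.990 and 0.988 for DMSO. They were 0.954, 0.931 and 0.993 for WIN, where WIN 2 and WIN 3 lay close together and WIN 1 apart. No pair of libraries was as close as the counting noise of the approximate reads alone, since the chi-square per degree of freedom over genes was at least 5.33 in all pairs. This does not show whether the libraries came from separate cultures.

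The comparison of WIN with DMSO asks how cannabinoid agonist exposure changes gene expression, and the study's title directs it to the translation initiation factors eIF2α and eIF2B1. With WIN, 25 of 30 integrated stress response targets and 18 of 24 endoplasmic reticulum chaperone and ERAD genes rose, and 17 of 23 cholesterol genes and 9 of 12 fatty acid synthesis genes fell. With 1 library left out in turn these counts ran from 19 to 27, 10 to 18, 8 to 18 and 3 to 12. The camera calls of these 4 lists were lost with an estimated correlation (adjusted p = 0.319, 0.319, 0.319 and 0.417). Among the 10 largest rises were Ddit3 (the stress transcription factor CHOP), Atf3 (a stress-induced transcription factor), Trib3 (a pseudokinase induced by CHOP) and Chac1 (a glutathione-degrading enzyme). Ddit3 rose from 42.0 ± 4.26 to 354.6 ± 134.7 CPM (n = 3 per group), a log2 fold change of 2.99 ± 0.31. Eif2b1, which encodes the alpha subunit of eIF2B, rose from 26.4 ± 1.27 to 96.7 ± 21.3 CPM.

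In all, 2354 of 10020 tested genes changed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 1272 higher and 1082 lower with WIN. The groups did not overlap for any of the 2354 genes. Across all tested genes, 43.5% had no overlap, while the chance for any given gene is 10% for 3 against 3. Differences between libraries are shared across genes, so the share can lie far from 10% without an effect of WIN and is no test. At least 2-fold changes were seen in 360 genes that rose and 345 that fell. The count depended on each library: it was 539 without DMSO 1, 626 without DMSO 2, 881 without DMSO 3, 6764 without WIN 1, 618 without WIN 2 and 1292 without WIN 3. All 2354 genes kept their sign in each of those 6 fits, which the lack of overlap made certain, so the sign is no separate test. Of 116 named genes past the threshold, 46 were kept without DMSO 1, 50 without DMSO 2, 54 without DMSO 3, 49 without WIN 2, 75 without WIN 3 and 116 without WIN 1. The median log2 fold change of all tested genes was -0.01.

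Bhlha15, a secretory-cell transcription factor known as MIST1, had the largest rise. It went from 0.369 ± 0.161 to 12.3 ± 2.32 CPM, a log2 fold change of 4.29 ± 0.25 (limma adjusted p = 0.000929). Il23a, a cytokine subunit, rose from 6.14 ± 0.808 to 78.7 ± 29.3 CPM. Amigo3, a neuronal adhesion molecule, rose by a log2 fold change of 2.87 ± 0.14. Gramd3 rose by 2.85 ± 0.17, and Aldh1l2, a mitochondrial folate enzyme, by 2.83 ± 0.15. Among the falls, Frmd4a had a log2 fold change of -3.09 ± 0.65, Kif26a (a kinesin family member) of -2.64 ± 0.33 and Sema6d (a semaphorin) of -2.55 ± 0.40. Mafb, a transcription factor, fell from 3.10 ± 0.0771 to 0.362 ± 0.226 CPM. Pik3r5 (a regulatory subunit of PI3 kinase gamma), Lgr5 (an R-spondin receptor), Kcnh1 (a potassium channel), Cyth3 (an exchange factor for ARF proteins), Ypel2 and Lca5 (a ciliary protein) had log2 fold changes of -2.35, -2.25, -2.23, -2.21, -2.18 and -2.08. The 10 rises and Kif26a, Mafb, Pik3r5 and Cyth3 stayed past the threshold whichever library was left out. Sema6d lost its call only without DMSO 1 (adjusted p = 0.0519). Frmd4a, Lgr5, Kcnh1, Ypel2 and Lca5 lost theirs without DMSO 1, DMSO 2 or WIN 2, among others for some, with adjusted p-values of up to 0.0896, 0.0813, 0.0691, 0.150 and 0.0747. Their WIN levels spread widely, at 5.56 ± 5.99, 6.69 ± 5.08, 5.51 ± 3.63, 4.55 ± 4.11 and 1.59 ± 1.09 CPM.

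The eIF2 and eIF2B subunits, which bind initiator tRNA and recharge eIF2 with GTP, had positive fold changes for all 8 members. Eif2b1, Eif2s1 and Eif2s2 rose and none fell. Eif2b1 had a log2 fold change of 1.84 ± 0.18 (limma adjusted p = 0.00252), with 25.3, 26.1 and 27.8 CPM in the DMSO libraries and 72.1, 109.7 and 108.3 CPM in the WIN libraries. Eif2s1, which encodes eIF2α, rose from 57.0 ± 3.90 to 85.8 ± 11.6 CPM, a log2 fold change of 0.58 ± 0.13 (limma adjusted p = 0.0227). Eif2s2, the beta subunit, had a log2 fold change of 0.94 ± 0.22. Adjusted over the list alone, 4 members rose, and 1 to 6 rose with 1 library left out. The list mean lay above the DMSO mean by 0.35 in WIN 1, 0.74 in WIN 2 and 0.73 in WIN 3 on the log2 scale. The list's median log2 fold change was 0.44 and camera placed it higher than other genes (adjusted p = 0.00677; adjusted p = 0.428 with an estimated correlation). Eif2b1 stayed past the threshold whichever library was left out. Eif2s1 did not, with adjusted p of 0.104 without DMSO 1, 0.103 without DMSO 2, 0.0608 without DMSO 3, 0.106 without WIN 2 and 0.0704 without WIN 3, and Eif2s2 was lost without the same libraries, with up to 0.113.

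Of 27 other initiation factors tested, 10 rose and 1 fell (13 and 2 adjusted over the list alone, and 3 to 20 and 0 to 4 with 1 library left out), with a median log2 fold change of 0.40 and a camera adjusted p of 0.000455 (adjusted p = 0.409 with an estimated correlation). The list mean was 0.22 in WIN 1, 0.42 in WIN 2, 0.43 in WIN 3 and 0.05 in DMSO 3, relative to the DMSO mean, and the median was 0.24 without DMSO 3, WIN 2 and WIN 3. Eif4ebp1, an inhibitor of cap-dependent translation and known ATF4 target, rose from 32.9 ± 2.61 to 119.3 ± 39.6 CPM. Eif5, an initiation factor, rose by a log2 fold change of 0.67 ± 0.08, whereas Eif4a1 (0.66 ± 0.14) and Eif6 (0.74 ± 0.21) lost the call without any 1 of the libraries other than WIN 1, with adjusted p of up to 0.102 and 0.173. Among 9 eIF2 kinases and phosphatase regulators, Ppp1r15a (GADD34, which directs dephosphorylation of eIF2α) rose from 80.1 ± 3.23 to 441.5 ± 142.5 CPM. Eif2ak4, the kinase GCN2, fell by a log2 fold change of -0.89 ± 0.21 and lost that call without any 1 of the libraries other than WIN 1 (adjusted p up to 0.116). Adjusted over the list alone, 3 of these 9 rose and 1 fell, and the list as a whole did not pass camera (adjusted p = 0.401).

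**Figure D1:**
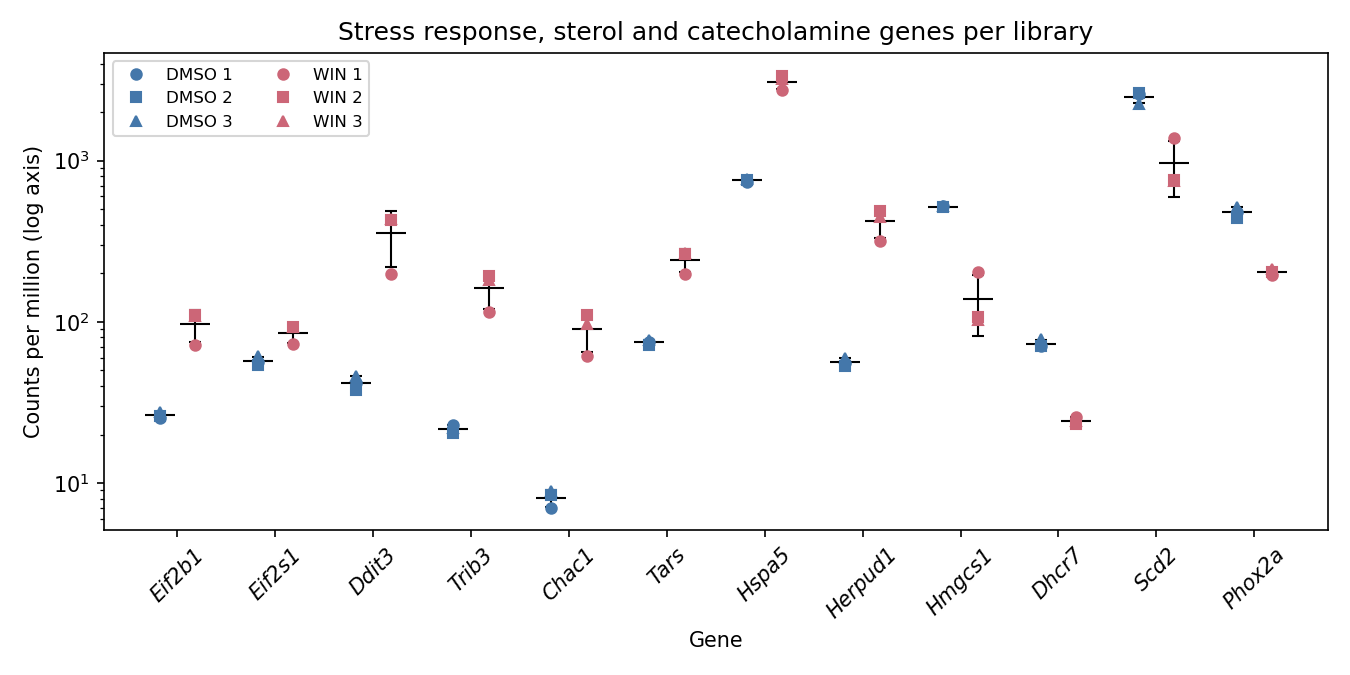
CPM of 12 genes in each library on a log axis, DMSO in blue and WIN in red, with black marks for the mean and SD of 3 libraries per group. Eif2b1 lay at 25.3 to 27.8 CPM in DMSO and at 72.1 to 109.7 CPM in WIN, and Hmgcs1, Dhcr7, Scd2 and Phox2a lay lower in all WIN libraries than in all DMSO libraries.

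Of 30 tested targets of the integrated stress response, 25 rose and none fell (27 and 0 adjusted over the list alone). With 1 library left out, 19 rose without DMSO 1 or WIN 2 and up to 27, with 1 that fell, without WIN 1. Their median log2 fold change was 1.61 and camera gave an adjusted p of 3.50e-15 (adjusted p = 0.319 with an estimated correlation). Atf3 had a log2 fold change of 3.41 ± 0.27, Chac1 of 3.39 ± 0.23 and Trib3 of 2.85 ± 0.20. The mean over the list lay above the DMSO mean by 1.43 in WIN 1, 1.82 in WIN 2 and 1.71 in WIN 3 on the log2 scale. The cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, included 14 of 20 that rose and none that fell (16 and 0 adjusted over the list alone), and 8 without DMSO 1 to 18 without WIN 1 that rose. Their median was 0.62 (camera adjusted p = 1.56e-08; adjusted p = 0.400 with an estimated correlation). Tars rose from 74.5 ± 2.36 to 243.2 ± 38.7 CPM, Sars by a log2 fold change of 1.19 ± 0.17, Cars by 1.16 ± 0.12 and Eprs by 0.99 ± 0.10. These 7 genes stayed past the threshold whichever library was left out.

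Endoplasmic reticulum chaperones and ERAD genes rose in 18 of 24 cases and none fell (18 and 0 adjusted over the list alone). Without DMSO 1, DMSO 2 or WIN 2 10 rose, and without WIN 1 18 rose and 4 fell. Their median log2 fold change was 0.75 (camera adjusted p = 2.49e-08; adjusted p = 0.319 with an estimated correlation). Hspa5, the chaperone BiP, rose from 753.5 ± 19.8 to 3093 ± 322.1 CPM, a log2 fold change of 2.03 ± 0.10 (limma adjusted p = 0.000929). Herpud1 (an ERAD component), Derl3 (a derlin of the same pathway) and Creld2 (a luminal protein induced by unfolded proteins) had log2 fold changes of 2.88, 2.82 and 2.64, and these 4 genes stayed past the threshold whichever library was left out. Cytosolic heat shock genes had fewer calls, although 12 of 17 had positive fold changes, and the lists were not tested against each other. Of 17 tested, Bag3 (a co-chaperone of HSP70) fell from 332.2 ± 12.5 to 159.2 ± 2.20 CPM, Dnaja1 fell by a log2 fold change of -0.35 ± 0.08, and none rose (the same counts adjusted over the list alone). The list did not pass camera (adjusted p = 0.594), and its median of 0.15 was positive while fry pointed down. Dnaja1 lost the call without any 1 of the libraries other than WIN 1 (adjusted p up to 0.121).

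Cholesterol synthesis and uptake genes fell in 17 of 23 cases and none rose (18 and 0 adjusted over the list alone), and 8 fell without DMSO 1, 9 without DMSO 2, 10 without WIN 2 and 18 without WIN 1. All 23 had negative fold changes, with a median of -0.95 (camera adjusted p = 7.54e-09; adjusted p = 0.319 with an estimated correlation). Hmgcs1, the synthase that supplies HMG-CoA, fell from 518.7 ± 5.75 to 137.8 ± 56.6 CPM, and Dhcr7, a late enzyme of the pathway, from 73.2 ± 4.13 to 24.4 ± 1.16 CPM. Ldlr, the LDL receptor, fell from 667.8 ± 77.9 to 246.7 ± 121.7 CPM and Stard4, a sterol carrier, by a log2 fold change of -2.06 ± 0.54. Fatty acid synthesis genes fell in 9 of 12 cases and in 12 of 12 adjusted over the list alone, but in 3 without DMSO 1 or DMSO 2, 4 without WIN 2 and 5 without DMSO 3, with a median of -0.78 (camera adjusted p = 3.88e-06; adjusted p = 0.417 with an estimated correlation). The desaturase gene Scd2 fell from 2484 ± 199.985 to 960.3 ± 361.2 CPM. Elovl6, Scd and Acly had log2 fold changes of -1.34, -0.95 and -0.84. The mean of the fatty acid list was -0.48 in WIN 1, -1.03 in WIN 2, -1.11 in WIN 3 and -0.10 in DMSO 3, relative to the DMSO mean. Hmgcs1 and Dhcr7 kept their calls whichever library was left out, while Ldlr, Stard4, Scd2, Elovl6, Scd and Acly reached adjusted p-values of up to 0.0850, 0.142, 0.0613, 0.138, 0.0797 and 0.104 without 1 library, DMSO 1, DMSO 2 and WIN 2 among them in each case.

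LXR and sterol efflux genes went both ways. Apoe, a lipoprotein component, rose from 0.604 ± 0.108 to 2.37 ± 0.433 CPM and Nr1h2, which encodes LXR beta, had a log2 fold change of 0.67. The sterol exporters Abca1 and Abcg1 fell by -1.98 and -0.61 on the log2 scale. Of these 7 genes 2 rose and 3 fell (3 and 3 adjusted over the list alone), the camera adjusted p was 0.888, and the median of -0.34 was negative while fry pointed up. Sphingolipid genes included 1 of 19 that rose and 4 that fell, and the same counts adjusted over the list alone (camera adjusted p = 0.188, fry adjusted p = 0.00324). Smpd3, neutral sphingomyelinase, fell from 105.3 ± 4.66 to 40.7 ± 12.6 CPM. Sphk1 (sphingosine kinase), Ugcg (glucosylceramide synthase) and Cers1 (ceramide synthase) had log2 fold changes of -1.38, -0.89 and -0.58. Apoe and Smpd3 stayed past the threshold whichever library was left out. Nr1h2, Abca1, Abcg1, Sphk1, Ugcg and Cers1 did not without DMSO 1, DMSO 2, DMSO 3 or WIN 2, with adjusted p-values of up to 0.168, 0.142, 0.145, 0.103, 0.107 and 0.127.

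Of 18 NGF-induced neuronal genes 6 fell and none rose, with the same counts adjusted over the list alone (0 to 10 fell with 1 library left out), and the median was -0.27 (camera adjusted p = 0.0132; adjusted p = 0.450 with an estimated correlation). The neurofilament genes Nefl, Nefm and Nefh had log2 fold changes of -0.87, -0.71 and -0.39, and Tubb3, neuronal beta tubulin, of -0.57. The list's call was lost without WIN 1 (adjusted p = 0.110). Catecholamine and chromaffin genes fell in 5 of 16 cases and none rose (9 fell and 1 rose adjusted over the list alone; 1 to 10 fell with 1 library left out, and 3 rose without WIN 1), with a median of -0.28 (camera adjusted p = 0.00677; adjusted p = 0.400 with an estimated correlation). Phox2a, a transcription factor of noradrenergic cells, fell from 477.5 ± 38.2 to 204.3 ± 8.37 CPM and Slc6a2, the noradrenaline transporter, from 92.4 ± 12.2 to 40.7 ± 19.3 CPM. Gata3 and Hand2, transcription factors of the same lineage, had log2 fold changes of -0.79 and -0.61. Of 17 synaptic vesicle genes, 4 fell and none rose, also adjusted over the list alone, and the list did not pass camera (adjusted p = 0.0630; 0.0497 without DMSO 3), with a mean of -0.11 in WIN 1, -0.49 in WIN 2, -0.58 in WIN 3 and -0.11 in DMSO 3. Cplx2 (a complexin), Stxbp1, Sv2a and Syn1 (a synapsin) had log2 fold changes of -0.89, -0.43, -0.41 and -0.30. Of the 12 genes named here, Phox2a stayed past the threshold whichever library was left out, and the others did not without DMSO 1, DMSO 2 or WIN 2, with adjusted p-values of up to 0.153.

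The receptor genes Cnr1, Cnr2 and Drd1 were below the filter and were not tested. The labels' treatment protocol also describes a D1 receptor agonist, while the series' design text gives only DMSO or WIN for these libraries. Cnr1 (CB1) was at 0.280, 0.303 and 0.0618 CPM in the DMSO libraries and at 0.0555, 0.0001 and 0.0337 CPM in the WIN libraries. Cnr2 (CB2) was at 0.0304 CPM in DMSO 2 and at the lowest value, 0.0001, in the 5 other libraries. Drd1, the D1 dopamine receptor, was at 0.0001 in all 6. Among 12 tested endocannabinoid genes, Dagla, which makes 2-arachidonoylglycerol, rose from 20.8 ± 1.13 to 32.8 ± 2.39 CPM and Abhd6, a hydrolase of the same lipid, fell from 35.5 ± 1.43 to 24.6 ± 1.36 CPM, with the same counts adjusted over the list alone (camera adjusted p = 0.424). Among 9 dopamine signalling genes, Adora2a (an adenosine receptor) and Prkar2b (a subunit of protein kinase A) fell by -0.92 and -0.81 on the log2 scale and none rose, with the same counts adjusted over the list alone (camera adjusted p = 0.278). Among 8 cAMP and CREB targets, Rgs4 (a regulator of G protein signalling) fell from 1226 ± 47.4 to 446.0 ± 99.6 CPM. Per1 (a clock gene) and Crem (a CREB family member) had log2 fold changes of 1.16 and 0.76, and 2 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.424). The mean of that list was 0.09 in WIN 1, -0.55 in WIN 2 and -0.63 in WIN 3. Adora2a, Rgs4 and Per1 stayed past the threshold whichever library was left out. Dagla, Abhd6, Prkar2b and Crem did not without DMSO 1 or WIN 2, among others, with adjusted p-values of up to 0.0638, 0.0824, 0.109 and 0.0831.

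Immediate early genes rose in 9 of 23 cases and fell in 4 (10 and 5 adjusted over the list alone; camera adjusted p = 0.101; 0.0101 with the stricter filter). Btg2, an antiproliferative gene, rose from 33.8 ± 1.06 to 92.4 ± 3.46 CPM and Ier2 by a log2 fold change of 1.03, while Egr3 fell by -1.16 and Klf10 by -1.06. Among 11 MAP kinase feedback genes, Dusp6 (an ERK phosphatase) and Spry4 (a receptor kinase inhibitor) fell by -1.04 and -1.02, and Etv5 rose by 0.37 (2 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.248). The mean of the latter list was -0.20 in WIN 1, -0.71 in WIN 2 and -0.87 in WIN 3. NRF2 genes rose in 4 of 20 cases and fell in 2 (5 and 2 adjusted over the list alone; camera adjusted p = 0.490), with Slc7a11, the cystine transporter that is also in the integrated stress response list, at 2.56 ± 0.30 and Nfe2l2, which encodes NRF2, at 0.87 ± 0.12. The p53 list had 4 of 17 that rose and 1 that fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.424), among them Gadd45a at 1.78, Aen at 1.16 and Sesn1 at -0.86. Of 21 apoptosis regulators 1 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.841). Hrk, a BH3-only activator of apoptosis, rose from 5.33 ± 0.541 to 13.1 ± 1.93 CPM, and Bmf, another BH3-only gene, and the caspase genes Casp6 and Casp3 had log2 fold changes of -1.98, -0.9997 and -0.68. Btg2, Slc7a11, Nfe2l2, Gadd45a, Aen, Sesn1, Hrk and Bmf stayed past the threshold whichever library was left out. Ier2, Egr3, Klf10, Dusp6, Spry4, Etv5, Casp6 and Casp3 did not without DMSO 1 or WIN 2, among others, with adjusted p-values of up to 0.139.

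Mitotic genes fell in 4 of 23 cases and none rose, also adjusted over the list alone (0 to 10 fell with 1 library left out, and 2 rose without WIN 1), with a median of -0.36 (camera adjusted p = 0.0174; adjusted p = 0.400 with an estimated correlation). Cenpf, Prc1, Ccna2 and Kif23 had log2 fold changes of -1.05, -0.93, -0.92 and -0.76. The list's call was lost without WIN 1 (camera adjusted p = 0.0601), with the covariate for long coding sequences (0.0854) and under quantile normalization (0.268), where the median was -0.09. It was also lost without DMSO 3, WIN 2 and WIN 3 and without DMSO 1, DMSO 2 and WIN 1. DNA replication genes rose in 5 of 25 cases and fell in 3 (6 and 3 adjusted over the list alone; camera adjusted p = 0.920), with Fen1 (flap endonuclease) at 1.35, Ung at 1.02, Mcm7 at 0.68 and Gins2 at -0.73. Autophagy and lysosome genes rose in 4 of 26 cases and fell in 3, also adjusted over the list alone (camera adjusted p = 0.150; 0.0494 without WIN 1), with Wipi1 at 0.80 and Atg7 at -0.50. Among 21 glycolysis and hypoxia genes, Hk2 (hexokinase) and Ankrd37 rose by 0.90 and 1.27 and Slc2a3 (the glucose transporter GLUT3) fell by -1.35, with the same counts adjusted over the list alone (camera adjusted p = 0.888). The medians of the NRF2, p53, apoptosis, DNA replication and glycolysis lists were 0.05, -0.04, 0.00, -0.07 and -0.02, and each took the other sign under at least 1 rescaling of the columns. The p53 list had a mean of 0.14 and the apoptosis list one of -0.11, opposite in sign to their medians, and fry pointed up for the DNA replication and glycolysis lists. Among 11 interferon-stimulated genes, Ddx58 (the RNA sensor RIG-I), Irf7, Stat2 and Stat1 fell by -1.05, -0.88, -0.81 and -0.58 and none rose (5 fell adjusted over the list alone; camera adjusted p = 0.149; 0.0330 without DMSO 2). None of 5 NF-kappaB genes passed, 1 had an unadjusted p under 0.05 and fry gave an adjusted p of 0.12 (camera adjusted p = 0.335), with Nfkb2 at 0.54 and Birc3 at 0.46. Fen1, Gins2, Wipi1 and Hk2 stayed past the threshold whichever library was left out, whereas the other genes named here that had passed did not without DMSO 1 (Stat2 only without that library), the highest adjusted p being 0.184 with any 1 library left out.

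**Figure D2:**
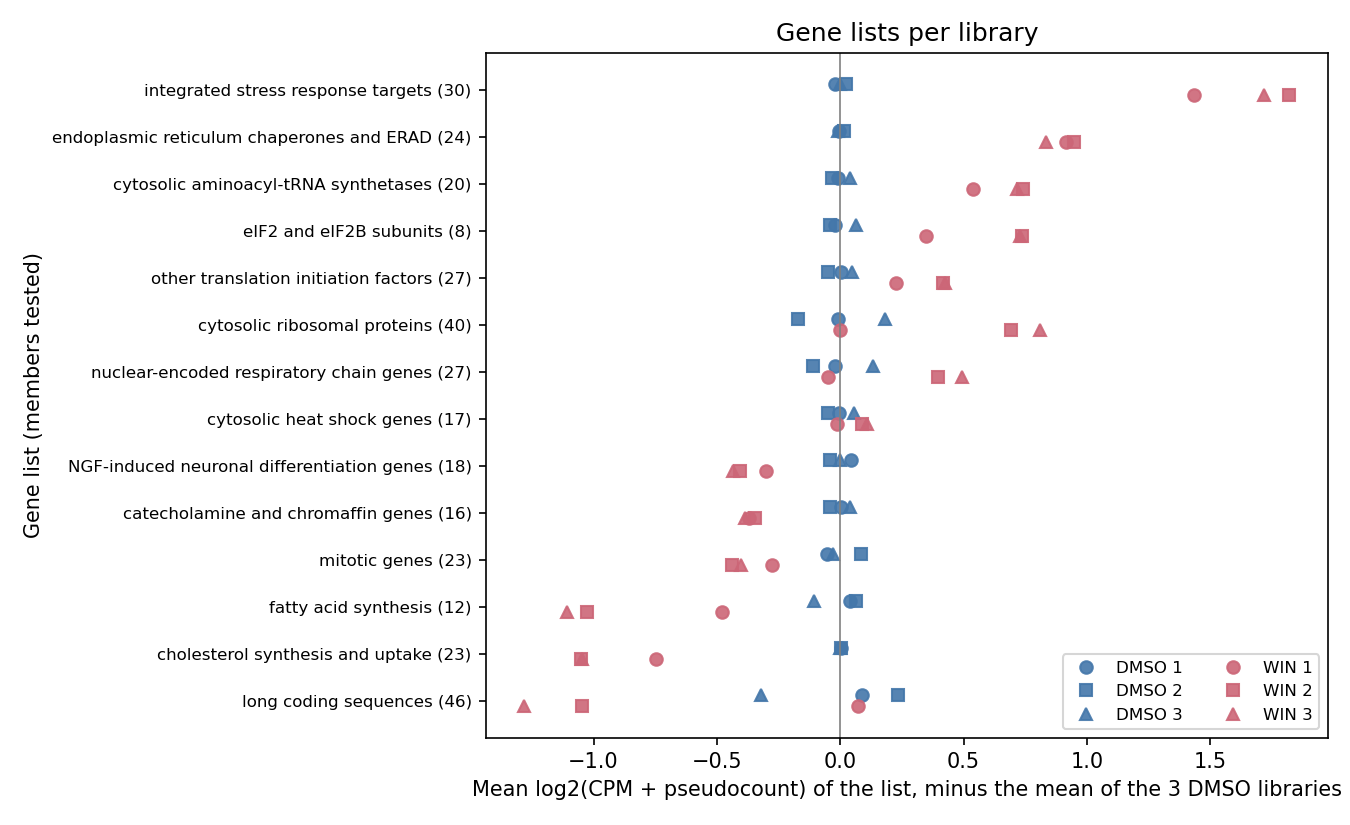
Mean log2(CPM + 0.281) of each gene list per library, minus the mean of the 3 DMSO libraries (x axis), for 14 lists (y axis, with the number of tested members), DMSO in blue and WIN in red. The integrated stress response list lay at 1.43, 1.82 and 1.71 in the WIN libraries and the ribosomal protein list at -0.00, 0.69 and 0.81.

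The means of the ribosomal protein and respiratory chain lists were higher in WIN 2 and WIN 3 but not in WIN 1, while some members were higher in WIN 1 too. The mean of 40 ribosomal protein genes, relative to the DMSO mean, was 0.69 in WIN 2, 0.81 in WIN 3, -0.00 in WIN 1 and 0.18 in DMSO 3. Its median fold change was 0.49 (camera adjusted p = 7.43e-06; adjusted p = 0.659 with an estimated correlation). None of the 40 passed limma's threshold, also adjusted over the list alone, 11 had an unadjusted p under 0.05, and fry gave an adjusted p of 0.175. Without WIN 1 all 40 rose (camera adjusted p = 9.12e-11), and none did without any other single library. Rps5 and Rpl30 had log2 fold changes of 0.70 and 0.58 with limma adjusted p of 0.0620 and 0.0941, and 9.20e-05 and 0.000897 without WIN 1. Rps5 was higher in all WIN libraries than in all DMSO libraries. It also passed limma's threshold under quantile normalization (adjusted p = 0.0406), with equal column totals (0.0480) and with the replicate block (0.0317). With the covariate for long coding sequences it had a log2 fold change of 0.26 (limma adjusted p = 0.000471). Respiratory chain genes included 2 of 27 that rose, Cycs (cytochrome c) at 0.56 and Ndufa10 at 0.47, and none adjusted over the list alone (24 rose and 1 fell without WIN 1, and none rose without any other single library; median 0.31; camera adjusted p = 0.00983; adjusted p = 0.680 with an estimated correlation). The respiratory chain call was lost without WIN 3 (camera adjusted p = 0.0788) and under quantile normalization (camera adjusted p = 0.0754). Cycs and Ndufa10 were higher in all WIN libraries than in all DMSO libraries. Their calls were lost without any 1 of the libraries other than WIN 1, with limma adjusted p of up to 0.170 and 0.179. The same libraries stood apart in genes with long coding sequences, a list of 46 written after the values were seen. Their mean was -1.05 in WIN 2, -1.28 in WIN 3 and -0.32 in DMSO 3, against 0.07 in WIN 1. Ribosomal RNA (Rn18s, Rn28s and Rn45s) took 2.50% of the column in WIN 2 and 2.61% in WIN 3, 0.441% in WIN 1 and 0.925% to 1.36% in DMSO. Without DMSO 3, WIN 2 and WIN 3, and with WIN 1 as the lone treated library, the medians of the ribosomal protein and respiratory chain lists were 0.08 and -0.00 (camera adjusted p = 0.108 and 0.898), the median of the integrated stress response list was 1.15, and 4301 genes were past the threshold.

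**Figure D3:**
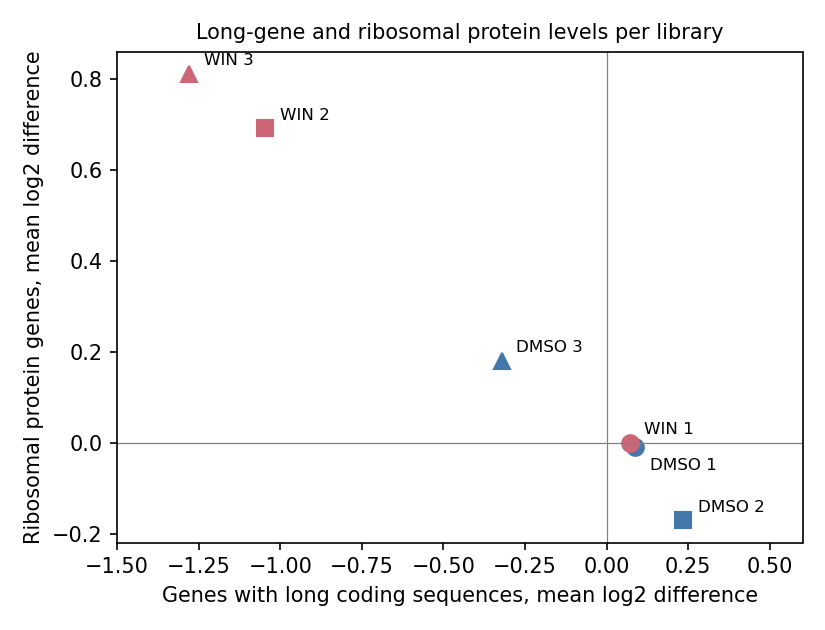
Mean log2 difference from the DMSO mean of 46 genes with long coding sequences (x axis) and of 40 ribosomal protein genes (y axis), 1 point per library. WIN 2 and WIN 3 lay at -1.05 and -1.28 on the x axis, and WIN 1 lay beside DMSO 1.

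None of the 13 mitochondrially encoded transcripts was among the row names. Of 3 tested non-polyadenylated RNAs none passed and none had an unadjusted p under 0.05. Rn18s was at 2564 ± 627.9 CPM in DMSO and 5583 ± 4151 CPM in WIN, and Rn28s at 3266 ± 650.5 and 4951 ± 3001 CPM. Without WIN 1 both passed, with adjusted p of 5.58e-05 and 0.000235. Markers of other cell types were mostly below the filter. Erbb3 was 1 of 3 tested glial markers to change, from 2.13 ± 0.181 to 0.634 ± 0.385 CPM. Cd68, the 1 tested macrophage marker, rose from 0.451 ± 0.150 to 1.61 ± 0.460 CPM, and the endothelial markers Cdh5 and Vwf fell from 13.8 ± 1.38 to 6.75 ± 2.63 CPM and from 4.15 ± 0.779 to 1.92 ± 0.498 CPM. None of 3 fibroblast markers passed limma's threshold, with Fbln1 at -0.14 and Thy1 at -0.02, and none had an unadjusted p under 0.05. Of 2 adrenal cortex markers none passed, with Scarb1 at -0.45 and Fdx1 at 0.42. 1 of them had an unadjusted p under 0.05 and 1 fell adjusted over the list alone, and counts of the other marker lists were the same adjusted over the list alone. Fdx1 passed without WIN 1 (adjusted p = 0.00764) and Scarb1 without WIN 1 or WIN 3 (0.0238 and 0.0376). Erbb3, Cd68, Cdh5 and Vwf lost their calls without DMSO 1, DMSO 2 or WIN 2, with adjusted p-values of up to 0.0963, 0.0783, 0.128 and 0.113.

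12 of the 30 lists tested with camera passed with the preset correlation. With a correlation estimated per list 0 passed (3 at an unadjusted p under 0.05), and fry, which asks whether a list's own genes move on balance one way and does not compare it with other genes, passed 15. The sphingolipid, dopamine signalling, p53, immediate early and synaptic vesicle lists passed fry but not camera (fry adjusted p = 0.00324, 0.00916, 0.00916, 0.0110 and 0.0110). The other splits of the 6 libraries into 3 and 3 gave 3 to 11 lists with the preset correlation. Counts in lists that did not pass also moved with 1 library left out: without WIN 1, 17 autophagy and lysosome genes, 12 immediate early genes, 10 NRF2 genes and 6 heat shock genes rose and 11 synaptic vesicle genes fell, while without DMSO 1 these counts were 1, 2, 2, 0 and 0.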

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

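Library subsets, the covariate for genes with long coding sequences and removal of ribosomal RNA were tests chosen after the data were seen. All 2354 changed genes kept their sign in every alternative per-gene fit, except that the stricter filter kept 2166 of them to fit, all with the same sign. Because the groups did not overlap for these genes, the sign could change only under the rescalings and the covariate. The count stayed between 2129 and 2453 under the pseudocounts, filters, scalings and the fit without a variance trend, was 2432 without ribosomal RNA and 1761 at 1.5-fold or more. It was 8747 with array weights, whose estimation stopped before convergence, and it ran from 539 to 6764 when 1 library was left out, with fewer libraries in each such fit. It was 4301 without DMSO 3, WIN 2 and WIN 3, 4914 without DMSO 1, DMSO 2 and WIN 1 and 4631 with the covariate, of which 2260, 2191 and 2308 were among the 2354; the library subsets left 1 residual degree of freedom and assumed that the lone sample varied like the other group. The share of higher calls was 54.0% in the full comparison and ran from 47.3% with the replicate block to 67.3% without DMSO 1. With an estimated correlation 0 lists passed camera, and 0 with the covariate as well (3 and 2 at an unadjusted p under 0.05). The eIF2 and eIF2B list (median 0.44) then had an adjusted p of 0.428 and the integrated stress response list (median 1.61) one of 0.319. Over all other alternatives those lists had adjusted p-values of up to 0.0260 and 0.000789. Rn18s reversed to -1.73 and Rn28s to -1.20 without DMSO 3, WIN 2 and WIN 3, and to -1.07 and -0.71 with the covariate, where the respiratory chain list reversed to a median of -0.0413 (adjusted p = 0.705). WIN 2 and WIN 3 held most of the ribosomal RNA, and for the other changes the cause was not tested. The immediate early list passed camera with the stricter filter and with the covariate (adjusted p = 0.0101 and 0.0392), the eIF2 kinase list without DMSO 3, WIN 2 and WIN 3 and with the covariate (0.00759 and 0.0170) and the synaptic list without a filter and without DMSO 1, DMSO 2 and WIN 1 (0.0496 and 0.0347), while the NGF-induced list was lost with array weights (0.0890). Over 126 named genes, 2118 gene-by-alternative results were on the same side of the threshold, 351 were lost and 35 gained, and 15 list-by-alternative results without a call changed direction.

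Whether replicate numbers pair the samples is not known from the labels. Deviations of same-numbered libraries from their group means had correlations of 0.448, -0.603 and 0.751 across genes. DMSO 3 deviated with both WIN 2 (0.681) and WIN 3 (0.751), the libraries that were also low in genes with long coding sequences. These correlations follow that difference between libraries, so they cannot show whether equal numbers shared a culture or a day. With the replicate block 2760 genes passed, 2051 of them among the 2354, and 12 lists. Not every library was closest to its own number. The count-based tests of WIN against DMSO planned in case whole reads could be recovered were not run. Depth is known only from the steps in the values. Cnr1, Cnr2 and Drd1 were below the filter and were therefore not compared.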

Other observations

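The tests of the gene groups, of the library split, of the falls, of the ribosomal protein shift and of the splits for changed genes were chosen after the results were seen. The splits for gene lists were chosen before their own results were seen. Members of the gene groups seen first were left out of each group's test, and the genes named in this paragraph were chosen after their values were seen. Genes of transport between the endoplasmic reticulum and the Golgi rose with WIN. Of 58 genes for COPII and COPI coats and their SNAREs, 40 rose and none fell, with a median log2 fold change of 0.66. Without the members seen first, 35 of 53 rose (camera adjusted p = 1.85e-13, and camera adjusted p = 0.0228 with an estimated correlation). All camera values in this paragraph were adjusted over only 3 lists, chosen after the results were seen. Those of the fixed lists were adjusted over 30, where the smallest with an estimated correlation was 0.319. The 0.0228 is therefore not comparable with them. Kdelr3, a retrieval receptor of luminal proteins, rose from 20.8 ± 1.96 to 92.2 ± 21.8 CPM and Sec24d, a cargo adaptor of COPII, from 52.7 ± 2.51 to 191.5 ± 23.1 CPM (n = 3). The list mean lay above the DMSO mean by 0.73 in WIN 1, 0.80 in WIN 2 and 0.74 in WIN 3, so it did not follow the split between WIN libraries. Of 42 genes for N-glycan precursors and the oligosaccharyltransferase, 14 rose and none fell. Without members seen first 12 of 40 rose (camera adjusted p = 0.00034; adjusted p = 0.237 with an estimated correlation). Gmppb, which makes GDP-mannose, rose from 12.9 ± 1.81 to 62.1 ± 6.44 CPM and Gnpnat1, an enzyme of the hexosamine pathway, from 9.26 ± 1.73 to 35.6 ± 2.92 CPM. Of 14 tubulin genes, 9 fell and none rose; without members seen first 6 of 11 fell (camera adjusted p = 0.0319; adjusted p = 0.422 with an estimated correlation). Tuba1a fell from 3187 ± 319.8 to 2076 ± 231.3 CPM, and Tubb2a by a log2 fold change of -0.61. Tubulin genes share sequence, so values of single members are uncertain. Counts with 1 library left out were not made for the 3 gene groups of this paragraph, so how far their counts depend on single libraries is not known.

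WIN 2 and WIN 3, and to a smaller extent DMSO 3, had low values of genes with long coding sequences. The mean of WIN 2 and WIN 3 minus WIN 1 was -1.23 on the log2 scale, and that of DMSO 3 minus the other DMSO libraries was -0.48. The list was written after the values were seen, to describe this split, so it does not test the cause, and loss of long transcripts stays open. The values argue against ribosomal RNA taking up reads, which would lower all other genes of a library alike. The mean of the ribosomal protein list was higher by 0.75 in WIN 2 and WIN 3 than in WIN 1, ribosomal RNA took at most 2.61% of a column, and its share in DMSO 3 (0.931%) lay between those in DMSO 1 and DMSO 2 (0.925% and 1.36%). A stronger drug response in WIN 2 and WIN 3 would not give the same differences among DMSO libraries, yet across genes these followed the differences among WIN libraries (Pearson r = 0.800, Spearman rho = 0.764, and genes are not independent replicates). A stronger response beside that shared difference is not excluded. The integrated stress response list had means of 1.43 in WIN 1, 1.82 in WIN 2, 1.71 in WIN 3 and -0.0015 in DMSO 3. The cholesterol list had -0.75, -1.05, -1.05 and -0.0022. The endoplasmic reticulum chaperone list did not move that way, at 0.92, 0.95, 0.83 and -0.008.

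The 1082 genes lower with WIN were set against that split. With the mean of the genes with long coding sequences as a covariate, 1053 of them stayed past the threshold with the same sign, and their median log2 fold change went from -0.79 to -0.62. The median of the genes that rose went from 0.79 to 0.60, so the shrinkage was not specific to the falls. The calls kept cannot weigh for or against loss of long transcripts. Genes that fell only along the split spread widely within groups and were unlikely to pass the first fit. The 1082 held 3 of the 46 genes with long coding sequences. The covariate took up that spread and raised the count of all changed genes to 4631. At least 900 of the 1082 stayed past the threshold under each of 4 rescalings, so most falls did not depend on the choice among these scalings. The median-of-ratios size factors ran only from 0.973 in DMSO 2 to 1.03 in WIN 2, so that rescaling hardly moved the columns. An error shared by all of these scalings was not tested. Loss of long transcripts and an effect of WIN both stay open, and transcript lengths were not analysed here.

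The shift of ribosomal protein and respiratory chain genes may follow the library split rather than the drug. With the covariate, the ribosomal protein list had a median of 0.04 and a camera adjusted p of 0.193, and without it the median was 0.49. The covariate came from a list written to describe this split, and the ribosomal protein list moved opposite to it in DMSO 3, WIN 2 and WIN 3. The shrinkage follows from that and does not weigh between the split and the drug. WIN 1 was the treated library beside the DMSO libraries in genes with long coding sequences. There the ribosomal protein list mean differed from the DMSO mean by -0.000122, and DMSO 1, DMSO 2 and DMSO 3 spanned -0.17 to 0.18. With 1 such treated library an effect of WIN cannot be told apart from the split.

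With 6 libraries there are 10 splits into 3 and 3, so a share under 0.05 cannot be reached. 1 split, the real one, gave as many as 2354 changed genes, and the highest of the others gave 0. At an unadjusted p under 0.05, 3269 genes differed when DMSO 1, DMSO 2 and WIN 1 were set against the rest, against 4211 in the real split, which points to the structure of the libraries described above. For gene lists, 1 split gave as many as 12 and the highest of the others gave 11 with the preset correlation of camera.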
